A study of Mus musculus with 35 samples.

How the data were processed

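Gene expression was measured in brown adipose tissue of control mice and of mice lacking Suv420h1 and Suv420h2, the enzymes that di- and trimethylate lysine 20 of histone H4 (Suv420h double knockout). Libraries were made from total RNA by oligo-dT priming with a 3' tag kit, per the labels' protocols, so each count stands for a tag near the 3' end of a transcript. The first experiment holds 15 libraries of mice aged 4 weeks and the second 20 libraries of female mice aged 21 weeks, 4 groups of 5, of which 2 groups had received a diet with 45 kJ% fat for 14 weeks. Nothing in the labels states that the replicates of a group are separate animals, so p-values measure only the spread between these samples, which may be technical.

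Per the submitters' processing notes, the reads were handled with STAR 2.5.3a, featureCounts and limma on mm10 and GRCm38. The gene annotation, the strand setting and the filters of that counting are not given in the sources used here. The authors deposited 1 table of raw counts per gene and library for each experiment, with whole numbers that were not normalised. The authors also deposited, for each experiment, a table of log2 fold changes of knockout over control. Those tables deposited by the authors further hold p-values and adjusted p-values per gene, for 10731 and 13251 genes. In the counts of the second experiment, 18 gene names had been turned into dates and held 0.09% of the counts. Each count column was matched to the sample whose description in the labels is the number in the column name, and 0 sample columns were left unmatched. No pair of libraries of the same group agreed within sampling noise, with a lowest chi-square of 5.19 per gene over genes with at least 20 counts in the pair.

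Total counts per library ranged from 3069035 to 8140213 in the first experiment and from 2398807 to 7693388 in the second. Genes were kept with the filterByExpr function of edgeR 4.0.16 (minimum count 10), which left 10366 of 10731 genes and 12082 of 13233 genes. Library sizes were scaled by TMM, and differences were tested with edgeR's quasi-likelihood test with robust dispersion in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, a gene was called at an adjusted p below 0.05, and standard errors were derived from the fold change and its F statistic. In the first experiment genotype and labelled sex entered 1 additive model. In the second, all 4 groups entered 1 model, which gave the genotype effect on each diet, the diet effect in each genotype and their interaction. Group levels are CPM, counts scaled to the TMM-adjusted library size, as mean ± SD. Values of single libraries for Suv420h1, Suv420h2 and Xist are CPM of the plain library total.

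For gene groups, 27 lists with 664 genes were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01), of which 541 and 577 genes were in the count tables. One list had fewer than 5 tested members, so 26 lists were tested per comparison, with Benjamini-Hochberg adjustment over the lists. With an inter-gene correlation estimated from the data, 0 lists passed in any of the 7 comparisons. The smallest adjusted p was then 0.240 for genotype and 0.908 for labelled sex in the first experiment. In the second it was 0.553 and 0.0857 for genotype on normal and high fat diet, 0.151 and 0.0669 for diet in control and knockout mice, and 0.314 for the interaction.

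The groups, tests, gene lists, the rule for the genes to be named and most alternatives were fixed before the data were examined. The rule names the targeted genes and the core genes Pparg, Ucp1, Ppargc1a, Cidea, Dio2 and Lep in every comparison. It adds the 7 highest and 7 lowest called fold changes among genes with a mean of at least 5 CPM, or 5 and 5 for labelled sex and the interaction, leaving out predicted genes, Rik clones, named pseudogene entries and plain identifiers. For each list past the threshold it adds the 3 members with the smallest adjusted p among called members, or, where none was called, the 2 with the largest absolute fold change. Lists not past the threshold are given as counts. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

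The procedure was tested on simulated data with 200 changed genes per comparison, 100 of them changed 2-fold and 100 changed 4-fold, on the real libraries' means and sizes. For genotype in the first experiment it recovered 69% of the 2-fold and 89% of the 4-fold changes with 9 false calls, and for labelled sex 65% and 86% with 8. For genotype in the second experiment it recovered 19% and 56% on normal diet with 1 false call, and 30% and 67% on high fat diet with 2. For diet it recovered 19% and 75% in control mice with 6 false calls, and 24% and 68% in knockout mice with 4. For the interaction it recovered 6% and 46% with 1 false call. A simulated changed list was called and 0 of 20 random lists were, in both experiments. The simulated genes were drawn independently of each other, so this could not test the preset inter-gene correlation. In the real data the estimated correlation reached 0.891, for skeletal muscle markers in the first experiment.

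Gene positions were taken from GENCODE M21 on GRCm38, in which 12199 of 12299 gene symbols (99.2%) had a match. The strand setting of the counting is not known, so genes that overlap another gene on the opposite strand, and genes with near-identical copies or pseudogenes, are uncertain. Besides those marked in the text, this holds for Acaa1b (Dlec1), Alas2 (Apex2), Als2cl (Tmie), Col4a2 (Col4a1), Ctsz (Nelfcd), Cyp51 (Akap9), Irf7 (Phrf1), Myh1 (Myhas), Myl3 (Pth1r), Myom1 (Myl12a), S100b (Dip2a), Sbk2 (Ssc5d) and Setdb1 (Cers2), each with its neighbour on the opposite strand, for Chst15 (Fgfr2), Hoxc8 (Hoxc5) and Per3 (Camta1), with a neighbour on the same strand, and for Cycs, Atp5c1 and Tpd52, with pseudogene copies. Some other genes named, among them Cidea, Dio2, Pparg, Ppargc1a and Suv420h1, overlap predicted genes or clones on the opposite strand. Alternatives planned in advance were DESeq2 1.42.0, limma-voom, RLE size factors, no count filter, the replicate number as a block, subsets of the samples, no term for sex, an estimated inter-gene correlation, genes of at least 5 CPM for the comparison of effects, and leaving out each library in turn. After seeing the data, fits with a library set, a skeletal muscle score or without certain libraries were added. Y-linked genes were not analysed here.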

Results

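Brown adipose tissue is the heat-producing fat depot, and the series compared it between control mice and mice lacking both Suv420h enzymes. The first experiment held 9 control libraries, 5 labelled female and 4 labelled male, and 6 knockout libraries, 5 labelled female and 1 labelled male, all from mice aged 4 weeks on normal diet. The second held female mice aged 21 weeks in 4 groups of 5 libraries: control and knockout, each on normal diet or on high fat diet for 14 weeks. Fold changes are log2 values of edgeR with 1 SE, and levels are CPM with SD.

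The targeted genes were examined first. Suv420h1 (annotated Kmt5b, chromosome 19, 3767421 to 3818303, GRCm38) and Suv420h2 (Kmt5c, chromosome 7, 4740115 to 4747514) were not analysed here in the first experiment. In the second, Suv420h1 stood at 42.4 ± 6.82 CPM in control and 39.5 ± 10.6 CPM in knockout libraries on normal diet, and at 31.7 ± 13.6 and 39.1 ± 7.14 CPM on high fat diet (SD, n = 5 each). Its fold changes were -0.10 (adjusted p = 0.838) for knockout on normal diet and 0.30 (adjusted p = 0.999) on high fat diet. Suv420h2 fell in the knockout on normal diet, from 49.9 ± 19.8 to 17.9 ± 4.71 CPM (-1.48 ± 0.34 SE, adjusted p = 0.0218). On high fat diet it stood at 17.6 ± 7.73 CPM in control and 10.4 ± 4.17 CPM in knockout libraries (-0.76 ± 0.34 SE, adjusted p = 0.913). A 3' tag outside the deleted part of a gene checks nothing about the deletion, and the position of the deleted part is not given in the sources used here.

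In single libraries, on the plain library total, Suv420h1 was 53.8, 42.3, 39.4, 35.9 and 41.6 CPM in control replicates 1 to 5 on normal diet and 30.7, 44.8, 43.5, 29.2 and 57.2 CPM in the knockout. Its values on high fat diet were 29.9, 21.8, 26.4, 23.3 and 61.2 CPM in control and 29.1, 49.9, 36.3, 35.3 and 35.3 CPM in knockout libraries. Suv420h2 was 75.1, 44.0, 28.9, 60.9 and 39.7 CPM in control and 20.5, 22.4, 10.5, 18.0 and 21.5 CPM in knockout libraries on normal diet. Its values on high fat diet were 11.0, 6.72, 22.5, 23.3 and 27.8 CPM in control and 4.38, 16.2, 10.4, 9.53 and 9.50 CPM in knockout libraries. The Suv420h2 call on normal diet was kept in 17 of 20 fits with 1 library left out and had a highest adjusted p of 0.0604, without knockout replicate 3 on normal diet. It was lost with a muscle score, the mean log2 CPM of skeletal muscle markers, as a covariate (-1.56, adjusted p = 0.0574) and without control replicates 2 and 4 on normal diet (-1.42, adjusted p = 0.0829), fits chosen after seeing the data. Over the alternatives with no single library left out its adjusted p ranged from 0.00149 to 0.0829.

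The first comparison asked how loss of both enzymes changes transcript levels in brown fat of young mice. Wdfy1, an adaptor protein of endosomes (chromosome 1, 79702262 to 79776143), rose from 9.42 ± 1.34 CPM in control (n = 9) to 48.4 ± 9.43 CPM in knockout libraries (n = 6), with a fold change of 2.34 ± 0.15 SE and adjusted p = 1.19e-08. Pttg1, which encodes securin, an inhibitor of sister chromatid separation (chromosome 11, 43420250 to 43426251), fell from 156 ± 59.6 to 7.33 ± 2.55 CPM (-4.14 ± 0.19 SE, adjusted p = 7.92e-11). Elovl3, a very long chain fatty acid elongase typical of brown fat (chromosome 19, 46131897 to 46135694), rose from 124 ± 102 to 494 ± 217 CPM (1.88 ± 0.33 SE, adjusted p = 0.0179). Ifi27l2a, an interferon-inducible gene (chromosome 12, 103442167 to 103443680), rose from 119 ± 58.2 to 289 ± 197 CPM (1.56 ± 0.22 SE, adjusted p = 0.00239). St6galnac5, a sialyltransferase (chromosome 3, 152817081 to 152982246), rose from 3.09 ± 0.80 to 11.3 ± 4.46 CPM (1.88 ± 0.25 SE, adjusted p = 8.89e-04).

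Further called increases at 4 weeks were Rps3a3 (5.65, adjusted p = 0.00501), Nnat (2.17, adjusted p = 0.0498) and Rpl39l (1.53, adjusted p = 0.00805). Rps3a3 is annotated as a processed pseudogene of a ribosomal protein gene inside Pde4d (chromosome 13, 108670603 to 108671397), and Nnat, an imprinted gene, overlaps Blcap on the opposite strand, so both are uncertain. Further called decreases at 4 weeks among genes with a mean of at least 5 CPM included S100a11, a calcium-binding protein (-1.41, adjusted p = 0.00727; 74.1 ± 23.8 against 24.6 ± 16.1 CPM), Tpd52 (-1.30, adjusted p = 0.0195) and Ggh, a folate hydrolase (-1.14, adjusted p = 0.0338). S100a11 has 1 pseudogene copy. Below that mean Eps8l1, chosen after its values were seen, fell further (-4.78, adjusted p = 3.71e-04). Fam214b (-0.94, adjusted p = 0.0102), the ubiquitin ligase gene Rnf213 (-0.94, adjusted p = 0.0492) and Arap1 (-0.93, adjusted p = 0.0302) also fell. The core genes of the tissue were not called. Ucp1, the uncoupling protein that produces heat, stood at 8342 ± 2429 CPM in control and 9459 ± 4169 CPM in knockout libraries (0.07, adjusted p = 0.907). Pparg, the master regulator of fat cells, had a fold change of -0.32 (adjusted p = 0.712), and its coactivator Ppargc1a 0.62 (adjusted p = 0.364). The brown fat gene Cidea had 0.32 (adjusted p = 0.444), the thyroid hormone deiodinase Dio2 0.70 (adjusted p = 0.479) and leptin, Lep, -0.29 (adjusted p = 0.870).

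In all, with sex in the fit, 52 genes rose and 34 fell in the knockout at 4 weeks. The count of 86 was 45 without control replicate 3, 51 without control 5, 33 without control 8, 18 without knockout 1, 147 without knockout 2, 47 without knockout 3 and 36 without knockout 4. Of the 14 called genes named by fold change, 7 were kept with any 1 library left out. Wdfy1 and Pttg1 alone were kept in all 12 other alternatives, but Pttg1 varied in older knockout mice (see Other observations). Elovl3 was lost without knockout 1 (adjusted p = 0.10), and so were Tpd52 (0.0550), Fam214b (0.0608) and Rnf213 (0.160) at their highest adjusted p. Nnat was kept in 3 of 15 such fits, with a highest adjusted p of 0.126 without control 8, Arap1 in 7 (0.0827 without control 8) and Ggh in 7 (0.0800 without control 3). The libraries also fell into 2 sets, given with the comparison of the labelled sexes. With the set in place of sex 218 genes were called, with the replicates labelled female alone 10, and with no term for sex 16. Within the set of 4 control and 2 knockout libraries 9 were called and within the set of 5 control and 4 knockout libraries 22.

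Of the 26 lists, 7 passed in the knockout at 4 weeks with sex in the fit, and none with an estimated correlation. Nuclear-encoded genes of oxidative phosphorylation rose as a list (61 of 76 positive, median 0.22, adjusted p = 2.47e-07; adjusted p = 0.283 with an estimated correlation). None of them was called over all genes and 4 were higher adjusted over the list alone. Cycs, cytochrome c, had a fold change of 0.54 (adjusted p = 0.238) and Atp5l, an ATP synthase subunit gene with 2 pseudogene copies, 2.65 (adjusted p = 0.302). No direction was read for Atp5l, whose mean was 712 CPM in control and 616 CPM in knockout libraries. Its fold change was -0.26 without knockout 2, -0.21 with no sex term, -0.26 with the library set in place of sex and -0.59 within the set of 9 libraries. Genes of PPAR-gamma and adipogenesis rose as a list (38 genes, median 0.11, adjusted p = 0.0352; adjusted p = 0.240 with an estimated correlation). No member was called over all genes, and 4 were higher adjusted over the list alone. Among them were the fatty acid binding protein Fabp3 (1.06, adjusted p = 0.122) and adiponectin, Adipoq (0.46, adjusted p = 0.0894). Cholesterol synthesis rose as a list (19 of 22 positive, median 0.28, adjusted p = 0.00697; adjusted p = 0.483 with an estimated correlation). No member was called over all genes or adjusted over the list alone. Its members Fdps and Sqle had fold changes of 1.27 (adjusted p = 0.229) and 0.70 (adjusted p = 0.222).

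Interferon-stimulated genes fell as a list (17 of 17 negative, median -0.30, adjusted p = 0.00211; adjusted p = 0.384 with an estimated correlation). Over all genes 0 members were called, and 1 was lower adjusted over the list alone. Usp18 had a fold change of -1.14 (adjusted p = 0.226) and Bst2 -0.93 (adjusted p = 0.394). Endothelial markers fell as a list (15 of 18 negative, median -0.22, adjusted p = 0.0277; adjusted p = 0.384 with an estimated correlation). No member was called over all genes or adjusted over the list alone. The angiopoietin receptor Tek had -0.50 (adjusted p = 0.349) and von Willebrand factor, Vwf, -0.48 (adjusted p = 0.455). Antioxidant genes rose as a list (20 genes, median 0.18, adjusted p = 0.0405; adjusted p = 0.321 with an estimated correlation). None of its members was called over all genes, and 4 were higher adjusted over the list alone. Its largest fold changes were -1.55 for the haem oxygenase Hmox1 (adjusted p = 0.307) and 1.52 for Gsta3 (adjusted p = 0.169). White fat selective genes rose as a list (9 genes, median 0.35, adjusted p = 0.0277; adjusted p = 0.321 with an estimated correlation). Nnat was its single called member, and 3 were higher adjusted over the list alone. The count of 7 lists was 2 without knockout replicate 1, 4 without knockout 6, 11 without knockout 3 and 13 without control 3. The other 19 lists did not pass.

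The labels of the first experiment also give a sex, and 3648 of 10366 genes tested differed between libraries labelled female and libraries labelled male. Tkt, transketolase of the pentose phosphate pathway, was higher in those labelled female (2.06 ± 0.26 SE, adjusted p = 7.79e-05), as were the acetyl-CoA carboxylase gene Acacb (0.98, adjusted p = 4.13e-04) and the mitochondrial citrate carrier Slc25a1 (0.94, adjusted p = 4.82e-04). The mitochondrially encoded mt-Rnr2 (-0.84, adjusted p = 0.00210), mt-Rnr1 (-0.97, adjusted p = 0.00442) and mt-Nd1 (-0.70, adjusted p = 0.00712) were lower in those labelled female. Cidea was higher (1.15 ± 0.21 SE, adjusted p = 7.11e-04). Ucp1 had a fold change of 0.52 (adjusted p = 0.0822), Pparg -0.87 (adjusted p = 0.0812), Ppargc1a 0.19 (adjusted p = 0.696), Dio2 0.36 (adjusted p = 0.592) and Lep 0.24 (adjusted p = 0.816). By the naming rule the highest called fold changes were those of Rps12 (6.89), Rpl28 (5.89), Cyp2u1 (5.73), Pigt (5.28) and the elastin gene Eln (5.05), with adjusted p of 4.01e-04, 2.94e-04, 1.62e-04, 1.74e-04 and 7.79e-05. The lowest were those of mt-Nd3 (-6.30), mt-Te (-5.40), Actg1 (-5.07), Gng5 (-5.03) and Atp5l (-4.89), with adjusted p of 0.0123, 0.00527, 0.00361, 0.00728 and 0.00843. Rps12 has 24 pseudogene copies, Rpl28 4, Atp5l 2 and Gng5 1, so these are uncertain.

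Lipogenesis genes were higher as a list in libraries labelled female (23 genes, 13 higher and 1 lower called, median 0.69, adjusted p = 9.58e-04; adjusted p = 0.908 with an estimated correlation). It had 13 higher and 1 lower adjusted over the list alone. Mitochondrially encoded transcripts were lower (10 genes, 1 higher and 7 lower called, median -0.71, adjusted p = 0.00994; adjusted p = 0.908 with an estimated correlation). It had 1 higher and 9 lower adjusted over the list alone. The other 24 lists did not pass. In all, 1841 genes were higher and 1807 lower in libraries labelled female. Xist, the RNA that silences an X chromosome in females (chromosome X, 103460366 to 103483254, with Tsix on the opposite strand), had a fold change of 2.78 ± 1.33 SE (adjusted p = 0.122) and went against the label in 2 libraries. The library labelled control male 6 held 236 CPM of Xist, and the other libraries labelled male held 1.89 to 4.79 CPM. The library labelled knockout female 2 held 1.57 CPM, and the other libraries labelled female 160 to 366 CPM.

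The 15 libraries separated along a first principal component with 52.8% of the variance. The set with the 5 libraries labelled male and knockout 2 took 27.4 to 30.1% of its counts from mitochondrially encoded genes and held 67.8 to 697 CPM of the mitochondrial tRNA gene mt-Te, against 14.1 to 20.4% and 1.35 to 7.76 CPM in the other 9 libraries. The sets coincide with columns 1 to 6 and 7 to 15 of the deposited counts. Only 1 library parts labelled sex from set. With the set beside sex in the model edgeR called 0 genes for labelled sex, with 310 at an unadjusted p below 0.05, and no other tool was run on that model. For single genes sex and set cannot be told apart.

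**Figure D1:**
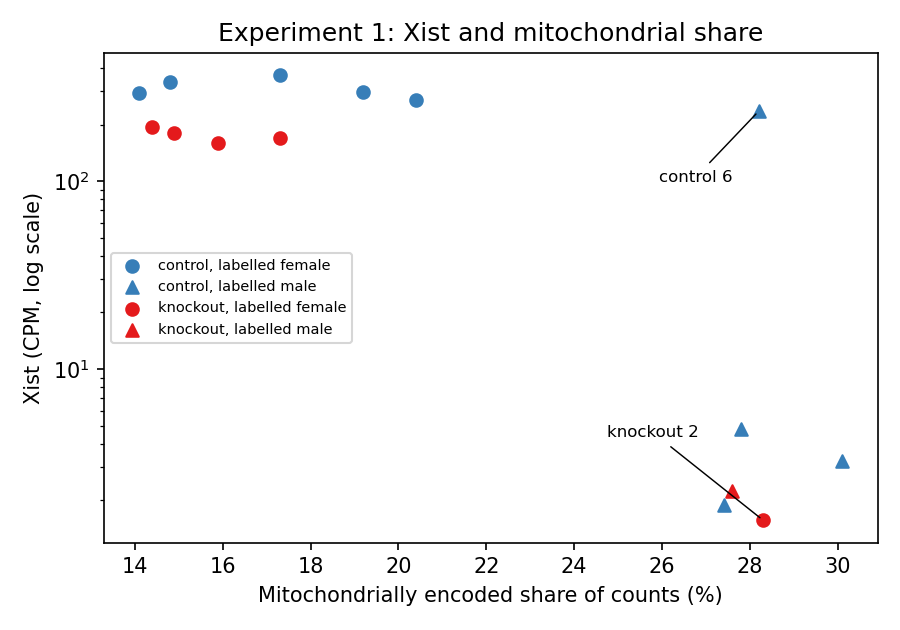
Xist (CPM of the plain library total, log scale) against the share of counts from mitochondrially encoded genes (%) in the 15 libraries of the first experiment, 1 point per library, coloured by genotype and shaped by labelled sex. The 6 libraries at 27.4 to 30.1% hold those labelled male and knockout 2, and control 6 (236 CPM) and knockout 2 (1.57 CPM) are marked.

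The second experiment asked about the genotype in older females on each diet. On normal diet, Wdfy1 rose from 7.03 ± 3.87 CPM in control to 45.5 ± 12.9 CPM in knockout libraries (2.63 ± 0.34 SE, adjusted p = 1.36e-04; n = 5 each). Ifi27l2a rose from 118 ± 42.3 to 749 ± 389 CPM (2.66 ± 0.31 SE, adjusted p = 1.23e-04). Mfsd2a, a lysophospholipid transporter, rose from 1.17 ± 1.65 to 42.2 ± 46.5 CPM (4.92 ± 1.07 SE, adjusted p = 0.0247), and Ffar4, a receptor for long chain fatty acids, from 11.7 ± 7.97 to 65.1 ± 42.7 CPM (2.42 ± 0.57 SE, adjusted p = 0.0330). Gfra1, a receptor for glial cell line-derived neurotrophic factor, rose (4.11 ± 0.89 SE, adjusted p = 0.0161), and so did the mitochondrial tRNA gene mt-Tc (4.41, adjusted p = 0.00231; 11.4 ± 7.48 against 242 ± 172 CPM) and Rps3a3 (6.14, adjusted p = 1.27e-04). Pparg had a fold change of 1.02 ± 0.29 SE with adjusted p = 0.0557, at 29.2 ± 13.1 CPM in control and 59.8 ± 12.3 CPM in knockout libraries. Ucp1 had -0.47 (adjusted p = 0.203), Ppargc1a 0.96 (adjusted p = 0.186), Cidea -0.24 (adjusted p = 0.564), Dio2 0.76 (adjusted p = 0.326) and Lep -0.27 (adjusted p = 0.897).

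Among genes with a mean of at least 5 CPM that the naming rule covers, the lowest called fold changes on normal diet included several genes of striated muscle. Myl3, a myosin light chain (chromosome 9, 110741861 to 110769798), fell from 844 ± 967 to 16.2 ± 11.0 CPM (-5.69 ± 1.36 SE, adjusted p = 0.0387). Junctophilin, Jph2 (-4.24, adjusted p = 0.0296), filamin C, Flnc (-3.77, adjusted p = 0.0459), myomesin, Myom1 (-3.69, adjusted p = 0.0406), Scn4b, a sodium channel subunit (-3.44, adjusted p = 0.0221), Sypl2 (-3.22, adjusted p = 0.0457) and Sbk2 (-3.05, adjusted p = 0.0138) fell as well. Skeletal muscle markers fell as a list (27 of 27 negative, median -4.12, adjusted p = 1.09e-12; adjusted p = 0.553 with an estimated correlation). It had 1 member called, Myl1 (-2.84, adjusted p = 0.0320), and 16 lower adjusted over the list alone. The muscle score, the mean log2 CPM of this list, was 6.31 ± 3.12 in control and 2.71 ± 2.01 in knockout libraries on normal diet (SD, n = 5 each), and the difference had an exact two-sided permutation p of 0.0714. It was 1.03 ± 2.92 and -0.15 ± 0.09 on high fat diet (exact p = 0.976).

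Cholesterol synthesis fell as a list on normal diet (19 of 22 negative, median -0.57, adjusted p = 0.00116; adjusted p = 0.553 with an estimated correlation). It had 1 higher and 3 lower called and 1 higher and 5 lower adjusted over the list alone. Insig1, a sterol-regulated protein that holds back the SREBP pathway (chromosome 5, 28071363 to 28078662), fell from 384 ± 211 to 101 ± 51.2 CPM (-1.92 ± 0.39 SE, adjusted p = 0.0141), and the synthesis enzymes Hsd17b7 (-1.40, adjusted p = 0.0105) and Cyp51 (-1.05, adjusted p = 0.0360) fell too. Fibroblast and matrix genes fell as a list (23 of 28 negative, median -0.54, adjusted p = 0.00193; adjusted p = 0.553 with an estimated correlation). It had 2 lower called and 1 higher and 5 lower adjusted over the list alone. Loxl1, which crosslinks elastin (chromosome 9, 58287738 to 58313186), fell from 54.9 ± 10.4 to 25.5 ± 7.89 CPM (-1.11 ± 0.23 SE, adjusted p = 0.0138), and the basement membrane collagen Col4a2 fell by 0.97 on the log2 scale (adjusted p = 0.0202). Other measures of the libraries also differed on this diet, from control to knockout (n = 5 each): the muscle score was lower, the mitochondrial share was 14.8 ± 2.7% and 18.6 ± 0.5% (SD), Gm42418, a locus of ribosomal RNA sequence, took 10.39 to 16.29% and 5.42 to 11.24% of counts, and genes with a read were 11401 to 12521 and 12416 to 12865. With it as a covariate the calls of Insig1 (-2.04, adjusted p = 0.0562), Hsd17b7 (-1.16, 0.102), Cyp51 (-1.10, 0.109) and Col4a2 (-1.02, 0.0641) were lost. Without control replicates 2 and 4 on normal diet those of Insig1 (-1.65, adjusted p = 0.0727), Cyp51 (-0.94, 0.14) and Col4a2 (-0.81, 0.105) were lost, and Loxl1 was kept in both fits. The matrix list did not pass in either (adjusted p = 0.465 and 0.122), and the cholesterol list did (4.25e-04 and 4.16e-04). The other 23 lists did not pass. The count of 3 lists ranged from 2, without control replicate 2 on normal diet, to 8, without control 3 on normal diet. It was 6 without control 1, knockout 4 or knockout 5 on normal diet, and 5 without control 4, knockout 2 or knockout 3 on normal diet, control 1, 2, 4 or 5 on high fat diet, or knockout 2 or 5 on high fat diet.

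In all, 156 genes rose and 164 fell in the knockout on normal diet. The count of 320 was 888 without control replicate 3 on normal diet, 170 without control 4, 175 without knockout 1, 127 without knockout 2, 146 without knockout 3, 160 without knockout 4 and 174 without knockout 5 of the same diet. With the muscle score as a covariate 51 genes were called, 49 of them among the 320, and without control replicates 2 and 4 on normal diet 84, with 65 among the 320. Both fits were chosen after seeing the data. Those 2 control libraries stood apart, with first principal component scores of 118 and 116.4 where the other 18 libraries reached at most 24.3. They had the fewest genes with a read (11401 and 11549) and the highest muscle scores (9.36 and 8.51) of the 20. Of the 21 named called genes, 5 were kept in both fits: Wdfy1, Ifi27l2a, Rps3a3, mt-Tc and Loxl1. With any 1 library left out, 10 of the 21 were kept. The highest adjusted p was 0.0847 for Cyp51, 0.0575 for Mfsd2a and 0.0754 for Ffar4, all without control 4 on normal diet. It was 0.0777 for Myl1, 0.0728 for Jph2, 0.105 for Flnc and 0.0623 for Scn4b without knockout 2, 0.0847 for Myl3 and 0.0887 for Myom1 without knockout 5, and 0.0993 for Sypl2 without control 2.

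On high fat diet, 12 genes rose and 2 fell in the knockout. Wdfy1 rose from 9.11 ± 2.65 to 49.4 ± 10.8 CPM (2.43 ± 0.33 SE, adjusted p = 3.35e-04; n = 5 each). St6galnac5 rose from 2.44 ± 1.19 to 11.0 ± 3.14 CPM (2.15 ± 0.41 SE, adjusted p = 0.0226), Akr1c13, an aldo-keto reductase (chromosome 13, 4191150 to 4205596), from 9.87 ± 4.36 to 32.9 ± 7.53 CPM (1.73 ± 0.30 SE, adjusted p = 0.00798), and Vat1l (chromosome 8, 114205612 to 114374071) from 6.76 ± 2.26 to 25.4 ± 5.75 CPM (1.91 ± 0.33 SE, adjusted p = 0.00760). Rps3a3 rose (5.15, adjusted p = 2.27e-04), and so did Hddc3 (2.01, adjusted p = 3.35e-04; 11.8 ± 1.48 against 47.4 ± 15.8 CPM), which overlaps Man2a2 on the opposite strand and is uncertain. Wdfy1 overlaps Mrpl44 and Gm10555 on the opposite strand, and St6galnac5 overlaps Pigk, so these are uncertain too. The called decreases, chosen after their values were seen, were Eps8l1 (chromosome 7, 4460674 to 4480487; -5.60, adjusted p = 0.00329) and Gm15510, an antisense gene. On normal diet Eps8l1 had 0 counts in all 5 knockout libraries against 7.48 ± 4.97 CPM in control, at least 60.3-fold lower with a floor of 3 counts over the group, or 0.124 CPM. The core genes had fold changes of 0.05 for Pparg, -0.26 for Ucp1, -0.01 for Ppargc1a, 0.06 for Cidea, 0.51 for Dio2 and -1.49 for Lep, each with adjusted p = 0.999. The call of St6galnac5 was kept in 14 of 20 fits with 1 library left out, and its highest adjusted p was 0.0944, without control 3 on high fat diet.

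Of the 26 lists, 11 passed in the knockout on high fat diet, 5 higher and 6 lower, with 0 members called over all genes in any of them. Except where given, 0 members passed adjusted over the list alone. The call of each list was lost with an estimated correlation. Peroxisomal lipid metabolism rose as a list (17 of 21 positive, median 0.29, adjusted p = 0.00136; adjusted p = 0.0857 with an estimated correlation). The list included Ehhadh at 1.91 (adjusted p = 0.711) and Acaa1b at 0.69 (adjusted p = 0.637). Mitochondrial fatty acid oxidation rose (21 of 24 positive, median 0.13, adjusted p = 0.00999; adjusted p = 0.546 with an estimated correlation). Members included the carnitine transporter Slc22a5 at 0.68 (adjusted p = 0.930). Clock genes rose (16 genes, median 0.49, adjusted p = 0.00625; adjusted p = 0.106 with an estimated correlation). Among its members were Ciart at 0.99 and Per3 at 0.95 (adjusted p = 0.861). Antioxidant genes rose (19 genes, median 0.23, adjusted p = 0.0153; adjusted p = 0.282 with an estimated correlation). Its members included the glutathione peroxidase Gpx3 at 0.76 (adjusted p = 0.572). PPAR-gamma and adipogenic genes rose (39 genes, median 0.13, adjusted p = 0.0478; adjusted p = 0.299 with an estimated correlation). It had 1 higher adjusted over the list alone. Its members included Klf15, a transcription factor of fat cells, at 1.40 (adjusted p = 0.0611) and Cd24a at -1.84 (adjusted p = 0.633).

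Interferon-stimulated genes fell as a list on high fat diet (17 of 18 negative, median -0.61, adjusted p = 2.79e-04; adjusted p = 0.0857 with an estimated correlation). The list included Usp18 at -1.14 and Irf7 at -1.04. Cholesterol synthesis fell (22 genes, median -0.22, adjusted p = 0.00223; adjusted p = 0.299 with an estimated correlation). Members included Sqle at -1.47 (adjusted p = 0.613) and Cyp51 at -0.82 (adjusted p = 0.518). Lipogenesis fell (23 genes, median -0.15, adjusted p = 0.0478; adjusted p = 0.558 with an estimated correlation). Among its members were Scd2 at -1.09 (adjusted p = 0.719) and Acly at -1.03 (adjusted p = 0.633). White fat selective genes fell (10 genes, median -0.47, adjusted p = 0.0478; adjusted p = 0.461 with an estimated correlation). Its members included Hoxc8 at -1.91 (adjusted p = 0.653). Erythroid markers fell (7 genes, median -0.49, adjusted p = 2.79e-04; adjusted p = 0.213 with an estimated correlation). It had 2 lower adjusted over the list alone. The list included Hba-a2 at -0.92 (adjusted p = 0.372). Muscle markers fell (26 of 27 negative, median -6.55, adjusted p = 0.00136; adjusted p = 0.558 with an estimated correlation). It had 12 lower adjusted over the list alone. Its members included Ckm at -8.94 (adjusted p = 0.613) and Ttn at -7.90 (adjusted p = 0.633). The muscle call rested on control replicate 3 on high fat diet, without which the list turned the other way (adjusted p = 0.811). With the muscle score as a covariate the lists of PPAR-gamma (adjusted p = 0.0993), lipogenesis (0.0836), fatty acid oxidation (0.0857), antioxidant (0.0788) and white fat genes (0.137) and muscle markers (0.825) were lost. The count of 11 lists was 6 without that library, and the other 15 lists did not pass.

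The diet was then compared within control mice. Scd1, which desaturates newly made fatty acids (chromosome 19, 44394455 to 44407879), fell from 12627 ± 3023 CPM on normal diet to 3590 ± 422 CPM on high fat diet (-1.81 ± 0.24 SE, adjusted p = 5.06e-04; n = 5 each). Fabp3, a fatty acid binding protein (chromosome 4, 130308595 to 130315463), rose from 1185 ± 105 to 2968 ± 819 CPM (1.32 ± 0.23 SE, adjusted p = 0.00679). Cpt1b, which admits fatty acids to mitochondria, rose from 283 ± 79.9 to 558 ± 116 CPM (0.98 ± 0.21 SE, adjusted p = 0.0278), and the carnitine carrier Slc25a20 rose (0.82, adjusted p = 0.0334). With the muscle score as a covariate Scd1 kept its call, and Fabp3 (1.20, adjusted p = 0.389), Cpt1b (0.66, 0.595) and Slc25a20 (0.57, 0.610) lost theirs. Gnas, the stimulatory G protein subunit (chromosome 2, 174284320 to 174346744, with Nespas on the opposite strand), rose from 334 ± 80.1 to 1138 ± 468 CPM (1.77 ± 0.25 SE, adjusted p = 0.00108). S100b rose from 205 ± 99.9 to 542 ± 121 CPM (1.41 ± 0.29 SE, adjusted p = 0.0236). Further called increases were Ifi27l2a (1.80, adjusted p = 0.00563), Hacd1 (1.70, adjusted p = 0.00207), Slc41a2 (1.5, adjusted p = 0.0356), Mtrf1l (1.38, adjusted p = 0.0391) and the lysosomal protease Ctsz (1.34, adjusted p = 0.00903).

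The lowest called fold changes of diet in control mice by the naming rule included Jph2 (-4.24, adjusted p = 0.0454), Sbk2 (-3.04, adjusted p = 0.0236), n-R5-8s1 (-2.78, adjusted p = 0.0334), Snhg11 (-2.47, adjusted p = 0.0193), desmin, Des (-2.40, adjusted p = 0.0488), and Sh3bgr (-2.17, adjusted p = 0.0334). Suv420h2 fell by 1.5 on the log2 scale (adjusted p = 0.0334) and Suv420h1 had -0.42 (adjusted p = 0.387). Ucp1 stood at 5859 ± 1433 CPM on normal and 9551 ± 1917 CPM on high fat diet (0.70, adjusted p = 0.0943) and Pparg at 29.2 ± 13.1 and 62.6 ± 15.6 CPM (1.09, adjusted p = 0.0690). Ppargc1a had 0.71 (adjusted p = 0.393), Cidea 0.02 (adjusted p = 0.978), Dio2 0.05 (adjusted p = 0.974) and Lep 1.06 (adjusted p = 0.603). The muscle score was 6.31 ± 3.12 on normal and 1.03 ± 2.92 on high fat diet (exact two-sided permutation p = 0.0238; 0.0635 after Benjamini-Hochberg adjustment over 4 comparisons). Muscle markers fell as a list (27 of 27 negative, median -3.71, adjusted p = 3.91e-26; adjusted p = 0.151 with an estimated correlation). Called over all genes were 0 members, and 16 were lower adjusted over the list alone. The list included Tnnt1 at -5.34 (adjusted p = 0.0932) and Tnni1 at -5.24 (adjusted p = 0.108).

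Measures of the libraries moved with diet in control mice. The mitochondrially encoded share of counts was 14.8 ± 2.7% on normal and 20.7 ± 3.5% on high fat diet (SD, n = 5 each). The share of Gm42418 was 10.39 to 16.29% against 6.17 to 11.31%, and 11401 to 12521 against 12873 to 13082 genes had a read. Lipogenesis fell as a list in control mice (21 of 23 negative, median -0.67, adjusted p = 4.54e-07; adjusted p = 0.151 with an estimated correlation). Scd1 was called, and it had 5 lower adjusted over the list alone. Fatty acid oxidation rose (22 of 24 positive, median 0.44, adjusted p = 6.12e-06; adjusted p = 0.305 with an estimated correlation). It had 2 called and 10 higher adjusted over the list alone. Brown fat genes rose (25 of 30 positive, median 0.49, adjusted p = 2.31e-04; adjusted p = 0.151 with an estimated correlation). It had 4 called and 8 higher adjusted over the list alone. Nuclear-encoded oxidative phosphorylation rose (68 of 76 positive, median 0.41, adjusted p = 8.82e-07; adjusted p = 0.520 with an estimated correlation). Atp5o (0.84, adjusted p = 0.0255) and Atp5c1 (0.72, adjusted p = 0.0334) were called, and it had 16 higher and 1 lower adjusted over the list alone. Mitochondrially encoded transcripts rose (10 genes, median 0.49, adjusted p = 0.0117; adjusted p = 0.53 with an estimated correlation). Over all genes 0 members were called, and 6 were higher adjusted over the list alone. Members included mt-Nd3 at 3.58 (adjusted p = 0.183) and mt-Cytb at 0.86 (adjusted p = 0.137). Interferon-stimulated genes rose (18 genes, median 0.60, adjusted p = 0.00337; adjusted p = 0.151 with an estimated correlation). Ifi27 was called (1.01, adjusted p = 0.0334), and it had 2 higher adjusted over the list alone. Cholesterol synthesis fell (22 genes, median -0.31, adjusted p = 0.0156; adjusted p = 0.520 with an estimated correlation). Insig1 was called (-1.71, adjusted p = 0.0392), and it had 1 higher and 3 lower adjusted over the list alone. Erythroid markers rose (7 genes, median 0.92, adjusted p = 0.00326; adjusted p = 0.357 with an estimated correlation). None of its members was called over all genes, and 4 were higher adjusted over the list alone. Among its members were Alas2 at 1.08 (adjusted p = 0.132) and Hba-a1 at 1.02 (adjusted p = 0.0603). The mitochondrially encoded (adjusted p = 0.307), erythroid (0.0541) and muscle lists (0.543) were lost with the muscle score as a covariate. The other 17 lists did not pass.

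In all, 49 genes rose and 47 fell with diet in control mice, and 5 of 100 divisions of these libraries, the real one included, gave as many calls. The count of 96 was 33, 21, 251 and 46 without control replicates 1, 2, 3 and 4 on high fat diet, 206, 31, 358, 52 and 150 without control replicates 1 to 5 on normal diet, and 55 without knockout 4 on high fat diet. With the muscle score as a covariate 2 genes were called, Scd1 and Vat1l, both among the 96, and without the outlying control replicates 2 and 4 on normal diet 25, with 18 among the 96. Scd1, Fabp3, Ifi27l2a, Gnas, Hacd1 and Ctsz were kept with any 1 library left out, and 17 of the 23 named called genes were lost in at least 1 such fit. The highest adjusted p without control replicate 2 on high fat diet was 0.161 for Des, 0.151 for Jph2, 0.150 for Insig1, 0.133 for Atp5c1, 0.125 for Ifi27, 0.121 for Suv420h2, 0.117 for Slc25a20, 0.116 for Sh3bgr, 0.106 for n-R5-8s1, 0.101 for Atp5o and 0.0867 for Sbk2. It was 0.119 for Mtrf1l and 0.0984 for Slc41a2 without control 1 on high fat diet, 0.0669 for Cpt1b and 0.0502 for S100b without control 4 on high fat diet, and 0.0615 for Snhg11 without control 2 on normal diet.

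In knockout mice, high fat diet raised Fabp3 from 1193 ± 399 to 3033 ± 783 CPM (1.35 ± 0.23 SE, adjusted p = 0.0124; n = 5 each) and Elovl3 from 290 ± 73.2 to 747 ± 174 CPM (1.36 ± 0.23 SE, adjusted p = 0.0122). Slc25a34, a mitochondrial carrier family member (chromosome 4, 141618824 to 141623821), rose from 8.03 ± 2.56 to 39.3 ± 12 CPM (2.28 ± 0.39 SE, adjusted p = 0.0124), and Loxl1 from 25.5 ± 7.89 to 80.1 ± 17.7 CPM (1.65 ± 0.23 SE, adjusted p = 0.00216). Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, fell from 710 ± 29.9 to 343 ± 109 CPM (-1.05 ± 0.24 SE, adjusted p = 0.0464). Dock8 (1.53, adjusted p = 0.0271), Adtrp (1.51, adjusted p = 0.0154), the retinol dehydrogenase Dhrs9 (1.5, adjusted p = 0.0230) and the R-spondin receptor Lgr6 (1.37, adjusted p = 0.0312) also rose. By the naming rule the lowest called fold changes were mt-Tc (-3.56, adjusted p = 0.0154), Rdh11, a retinal reductase (-1.96, adjusted p = 0.0154), Als2cl (-1.95, adjusted p = 0.0312), the neurotrophin receptor Ntrk3 (-1.83, adjusted p = 0.0154), Flywch1 (-1.52, adjusted p = 0.0313), Impdh1, an enzyme of guanine nucleotide synthesis (-1.45, adjusted p = 0.0154), and Chst15 (-1.38, adjusted p = 0.0313). Ucp1 had a fold change of 0.92 ± 0.21 SE (adjusted p = 0.0531), Pparg 0.12 (adjusted p = 0.959), Ppargc1a -0.25 (adjusted p = 0.930), Cidea 0.32 (adjusted p = 0.751), Dio2 -0.20 (adjusted p = 0.953), Lep -0.16 (adjusted p = 0.984), Suv420h1 -0.02 (adjusted p = 0.994) and Suv420h2 -0.78 (adjusted p = 0.478).

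Of the lists, 10 passed for diet in knockout mice, 6 higher and 4 lower. Measures of the libraries also differed, from normal to high fat diet (n = 5 each): genes with a read were 12416 to 12865 and 12873 to 13064, the mitochondrial share was 18.6 ± 0.5% and 22.1 ± 3.9% (SD), and Gm42418 took 5.42 to 11.24% and 5.06 to 9.68% of counts. Lipogenesis fell (22 of 23 negative, median -0.52, adjusted p = 3.04e-07; adjusted p = 0.175 with an estimated correlation). Acaca was called, and it had 6 lower adjusted over the list alone. Fatty acid oxidation rose (24 of 24 positive, median 0.34, adjusted p = 1.66e-06; adjusted p = 0.175 with an estimated correlation). No member was called over all genes, and 1 was higher adjusted over the list alone. Its members included Cpt1a at 0.86 (adjusted p = 0.431) and Cpt1b at 0.86 (adjusted p = 0.0702). Brown fat genes rose (30 genes, median 0.29, adjusted p = 6.05e-06; adjusted p = 0.0669 with an estimated correlation). Elovl3 and Fabp3 were called, and it had 7 higher and 1 lower adjusted over the list alone. Elovl3 overlaps Pitx3 and Fabp3 overlaps Zcchc17 on the opposite strand, and Fabp3 has 1 pseudogene copy, so both are uncertain. PPAR-gamma and adipogenic genes rose (39 genes, median 0.14, adjusted p = 0.0121; adjusted p = 0.175 with an estimated correlation). It had 1 called and 2 higher adjusted over the list alone. Peroxisomal genes rose (21 genes, median 0.24, adjusted p = 0.00128; adjusted p = 0.0999 with an estimated correlation). No member was called over all genes or adjusted over the list alone, and it included Ehhadh at 2.36 (adjusted p = 0.216) and Pecr at 0.90 (adjusted p = 0.334). Mitochondrially encoded transcripts rose (10 genes, median 0.56, adjusted p = 3.71e-05; adjusted p = 0.175 with an estimated correlation). Over all genes 0 members were called, and 4 were higher adjusted over the list alone. The list included mt-Nd3 at 1.17 (adjusted p = 0.866) and mt-Nd2 at 0.73 (adjusted p = 0.0988). Nuclear-encoded oxidative phosphorylation rose (76 genes, median 0.10, adjusted p = 0.0327; adjusted p = 0.802 with an estimated correlation). No member was called over all genes or adjusted over the list alone, and it included Sdhd at 1.41 (adjusted p = 0.597) and Cycs at 0.53 (adjusted p = 0.535).

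Immediate early genes fell in knockout mice on high fat diet (17 genes, median -0.57, adjusted p = 0.0130; adjusted p = 0.343 with an estimated correlation). None of its members was called over all genes, and 2 were lower adjusted over the list alone. Members included Egr1 at -2.97 (adjusted p = 0.185) and Nr4a1 at -2.74 (adjusted p = 0.427). Genes of H4K20, H3K9 and HP1 chromatin fell (19 genes, median -0.16, adjusted p = 0.0225; adjusted p = 0.175 with an estimated correlation). None of its members was called over all genes or adjusted over the list alone. Members included the H3K9 methyltransferase genes Setdb1 at -0.82 (adjusted p = 0.733) and Ehmt2 at -0.75 (adjusted p = 0.505). Muscle markers fell (27 genes, median -5.76, adjusted p = 2.13e-10; adjusted p = 0.350 with an estimated correlation). Over all genes 0 members were called, and 12 were lower adjusted over the list alone. Among its members were Ttn at -8.24 (adjusted p = 0.268) and Ckm at -7.92 (adjusted p = 0.342). The muscle score differed by -2.85 between the diets (exact two-sided permutation p = 0.0317; 0.0635 after adjustment over 4 comparisons). With it as a covariate the lists of nuclear-encoded oxidative phosphorylation (adjusted p = 0.623) and muscle markers (0.874) were lost. The other 16 lists did not pass.

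In all, 22 genes rose and 23 fell with diet in knockout mice. The count of 45 was 6, 26, 11 and 13 without knockout replicates 1, 2, 4 and 5 on high fat diet, and 19, 14, 29 and 28 without knockout replicates 2, 3, 4 and 5 on normal diet. With the muscle score as a covariate 9 genes were called, 8 of them among the 45, and without control replicates 2 and 4 on normal diet 100, among them all 45. Elovl3, Fabp3, Slc25a34 and Loxl1 were kept with any 1 library left out, but Fabp3 was lost with the muscle score as a covariate (1.28, adjusted p = 0.0559), and 12 of the 16 named called genes were lost in at least 1 fit. The highest adjusted p was 0.151 for Acaca without knockout 4 on high fat diet, 0.103 for Dock8 and 0.0664 for mt-Tc without knockout 5 on high fat diet. It was 0.10 for Dhrs9 and for Als2cl, 0.0665 for Rdh11 and 0.0597 for Ntrk3 without knockout 1 on high fat diet, 0.129 for Flywch1 without knockout 2 on normal diet, and 0.0618 for Adtrp, 0.0950 for Lgr6, 0.0661 for Impdh1 and 0.123 for Chst15 without knockout 3 on normal diet.

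**Figure D2:**
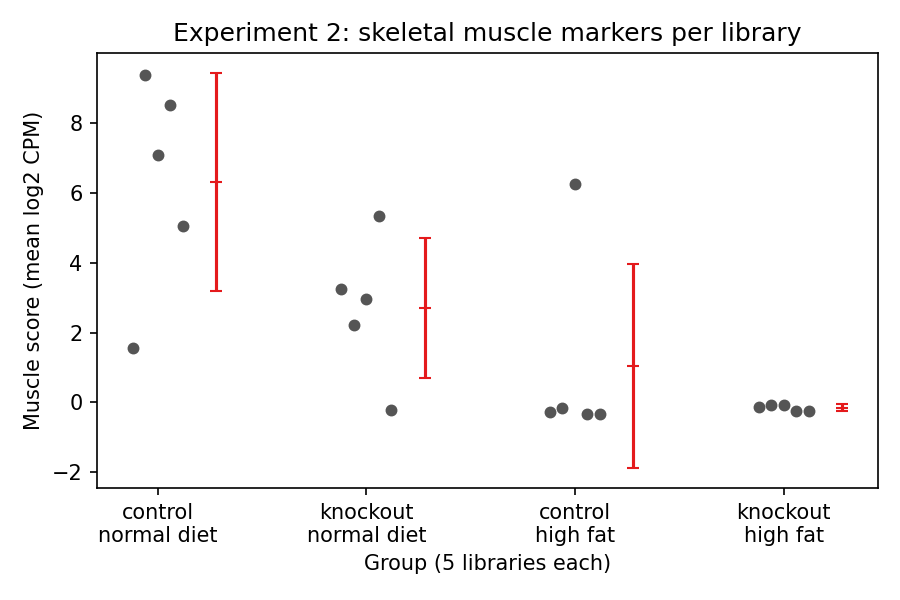
Muscle score (mean log2 CPM of 27 skeletal muscle markers) of each of the 20 libraries of the second experiment by group, 1 point per library, with the group mean and SD in red. Control libraries on normal diet averaged 6.31 ± 3.12, and 1 control library on high fat diet stood at 6.26 where the next was at -0.17.

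The interaction asked whether the diet effect differed between the genotypes. By edgeR 0 genes were called, with 772 at an unadjusted p below 0.05; DESeq2 called 12 and limma-voom 0, and edgeR called 2 genes without control replicate 5 on normal diet and 1 without control 2 on high fat diet. The simulated data gave 46% recovery of 4-fold and 6% of 2-fold differences, so smaller differences were mostly not detectable. Ucp1 had an interaction of 0.21 (adjusted p = 0.930), Pparg -0.97 ± 0.41 SE (adjusted p = 0.767), Ppargc1a -0.96 (adjusted p = 0.830), Cidea 0.30 (adjusted p = 0.904), Dio2 -0.25 (adjusted p = 0.967), Lep -1.22 (adjusted p = 0.904), Suv420h1 0.41 (adjusted p = 0.879) and Suv420h2 0.72 (adjusted p = 0.850).

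As lists, 5 of 26 passed for the interaction, with 0 members called over all genes and, except where given, 0 adjusted over the list alone. Oxidative phosphorylation was lower (63 of 76 negative, median -0.28, adjusted p = 0.00696; adjusted p = 0.694 with an estimated correlation). Its members included Atp5g1 at 2.52 (adjusted p = 0.750) and Cox7c at -1.39 (adjusted p = 0.844). Interferon-stimulated genes were lower (18 genes, median -0.91, adjusted p = 0.00337; adjusted p = 0.314 with an estimated correlation). The list included the RNA sensor Ifih1 at -1.77 (adjusted p = 0.750) and Ifit2 at -1.76 (adjusted p = 0.874). Erythroid markers were lower (median -1.11, adjusted p = 0.00696; adjusted p = 0.694 with an estimated correlation). It had 2 lower adjusted over the list alone. The list included Hbb-bt at -1.37 (adjusted p = 0.767) and Alas2 at -1.24 (adjusted p = 0.767). Matrix genes were higher (21 of 28 positive, median 0.44, adjusted p = 0.00696; adjusted p = 0.694 with an estimated correlation). It had 1 higher adjusted over the list alone. Members included Mfap5 at 1.74 (adjusted p = 0.767) and Thbs1 at 1.30 (adjusted p = 0.895). For muscle markers the median (-1.85) and mean (-1.36) were negative and the test pointed up (adjusted p = 1.63e-07; adjusted p = 0.694 with an estimated correlation). No direction was read from it. Ckm stood at -5.34 (adjusted p = 0.850) and Myh1 at -4.01 (adjusted p = 0.881). The list of interferon-stimulated genes alone passed with the muscle score as a covariate (adjusted p = 0.00381). The other 21 lists did not pass.

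The genotype effects of the experiments, which share no libraries, were compared across genes, which are not independent replicates. Between the first experiment and the second on normal diet the fold changes of 10149 genes had Pearson's r = 0.153 and Spearman's rho = 0.095, with 9 genes called higher in both (0.62 for independent lists) and 4 called lower in both (0.48). Against high fat diet r was 0.269 and rho 0.252, with 5 genes called higher in both (0.055) and 1 lower (0.0033). Between the diets of the second experiment r was 0.528 and rho 0.339 over 12082 genes. There 6 genes were called higher in both diets (0.15 for independent lists), Akr1c13, Car3, Hddc3, Rps3a3, Wdfy1 and 1700030C10Rik, and 2 lower (0.027), Eps8l1 and Gm15510, named after their values were seen. The diet effects in control and knockout mice had r = 0.473 and rho = 0.288, with Ctsz, Fabp3, Gnas, Lgr6, Prelp and S100a13 called higher in both (6 against 0.089) and Cyp1a1 and Flywch1 lower (2 against 0.089).

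**Figure D3:**
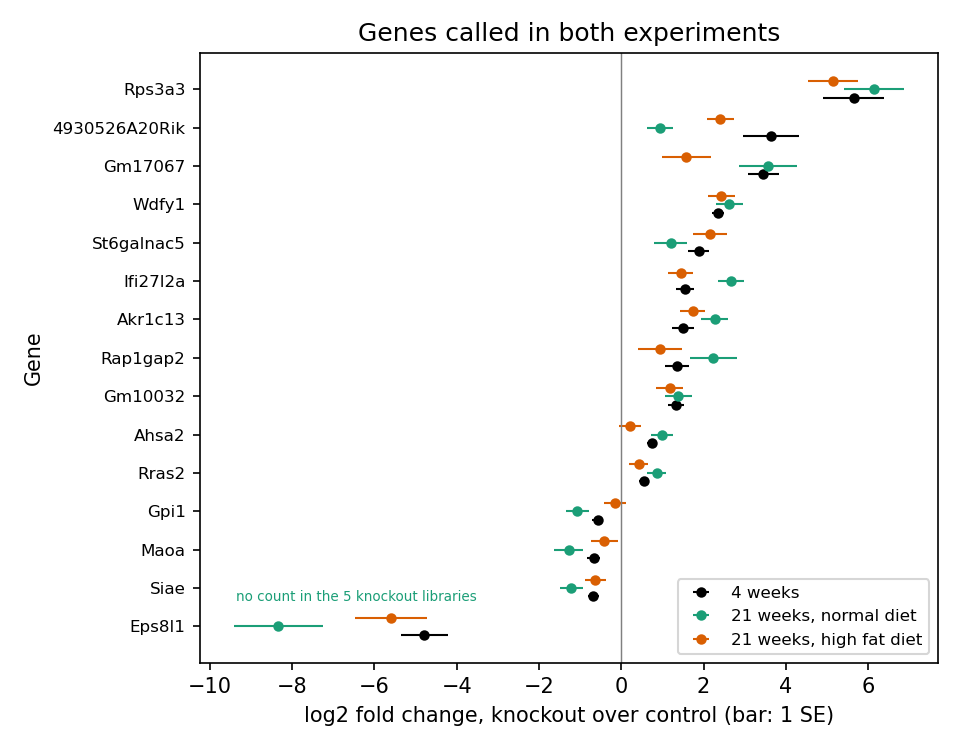
Log2 fold change of knockout over control with 1 SE (horizontal bars) for the 15 genes called in the first experiment and in at least 1 diet of the second, by comparison. Wdfy1 lies at 2.34, 2.63 and 2.43, and Eps8l1 had 0 counts in the 5 knockout libraries on normal diet, so its fitted value there is no bound.

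The authors' deposited tables of knockout over control held 293 higher and 168 lower genes at their adjusted p below 0.05 in the first experiment, among them 81 of the 86 called here, and 245 higher and 221 lower in the second, among them 183 of the 320 called here on normal diet. In the authors' deposited tables Wdfy1 had log2 fold changes of 2.32 and 5.21, Ifi27l2a 1.29 and 3.87, and, in the first experiment, Pttg1 -4.36 and Elovl3 2.09. Their deposited table of the second experiment gave Suv420h2 -1.93 (adjusted p = 0.0149) and Suv420h1 0.21 (adjusted p = 0.742). Across genes, the authors' deposited folds of the first experiment had r = 0.931 and a slope of 0.959 with the fit that held the library set, against r = 0.767 and a slope of 0.628 with the fit that held labelled sex. The authors' deposited folds of the second experiment lay closer to the sum of the effects on both diets (median absolute difference 0.146) than to their mean (0.312).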

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

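All tests in this part were chosen after the result they bear on was seen, apart from the interaction, which was planned. Of 84 sets of values, 1 per group and measure, 11 had a library whose gap to its neighbour was large against the range of its group by Dixon's test, and chance gives about 0.05 of the sets. In the first experiment, Pparg stood at 197 CPM in control 1 (next 41.7), Lep at 45.7 CPM in control 2 (next 18.6) and Ucp1 at 17591 CPM in knockout 5 (next 9419). On high fat diet, control 5 had the lowest total of its group, 4.68 M counts against 6.09 M in the next (M is 10 to the power 6), and a Suv420h1 level of 55.4 CPM (next 31.2). In the knockout on high fat diet, replicate 2 had 51.3 CPM of Suv420h1 (next 37.7) and 24.0 CPM of Pparg (next 66.6), and replicate 1 had 11089 CPM of Ucp1 (next 7367). In the knockout on normal diet, Lep stood at 13.2 CPM in replicate 5 (next 2.12) and Pttg1 at 38.8 CPM in replicate 1 (next 4.74).

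The diet effect differed between the genotypes for 5 lists by the interaction test. The adjusted p was 0.00696 for oxidative phosphorylation, erythroid markers and matrix genes, 0.00337 for interferon-stimulated genes and 1.63e-07 for muscle markers. None passed with an estimated correlation (lowest adjusted p = 0.314).

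The mean muscle score was lower in the knockout on normal diet, and lower on high fat diet than on normal diet in each genotype, while on high fat diet the genotype difference rested on control 3 (6.26, where the next library of the group stood at -0.17). Within groups the markers moved together, with an inter-gene correlation of 0.877, as muscle tissue carried along in some libraries would give, so this is a candidate explanation. An effect of genotype stays open, since the exact permutation p of the score was 0.0714 on normal diet and 0.976 on high fat diet, and neither shows that the groups were alike. For diet the score differed by -5.28 in control (exact permutation p = 0.0238) and -2.85 in knockout mice (0.0317), both 0.0635 after adjustment over 4 comparisons, so an effect of diet also stays open.

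The first experiment fell into 2 sets of libraries, of 6 and 9. Reads shared with near-identical pseudogene copies may contribute. Of genes with a named copy, 16.5% (38 of 231) changed over 4-fold between the labelled sexes, against 1.6% (156 of 9848) of other genes, an odds ratio of 12.2 (95% CI 8.11 to 18.1, Fisher's exact p = 3.6e-25). For single genes the labelled sex and the set cannot be told apart, because 1 library alone parts them. Xist in control 6 and knockout 2 goes against their labels, and Y-linked genes were not analysed here.

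Other divisions of the libraries into groups of the same sizes were drawn, 100 per comparison with the real one included. For counts of genes, labelled sex (3648 real, highest other 0) follows the library sets, so this cannot test sex. For genotype at 4 weeks (86, 30) chance is weakly excluded, at 18 to 147 with 1 library left out. So it is for genotype on normal diet (320, 28; 127 to 888) and diet in knockout mice (45, 1; 6 to 67). With the muscle score 49 and 8 of these were kept, so uneven muscle stays open. Chance could be excluded for genotype on high fat diet (14, 1). It could not for diet in control mice (96, 914), where 5 of 100 gave as many. The division with 914 set control replicates 1, 2 and 3 on high fat diet and 3 and 5 on normal diet against the rest, which points to a structure of the samples. The interaction (0, 2 by edgeR) decided nothing, since any division gives as many as 0. For counts of lists, under 5 of 100 gave as many only for genotype on high fat diet (11 real, highest other 12; 4 of 100), where another division gave more, the count was 6 without control 3 on that diet and 0 lists passed with an estimated correlation (smallest adjusted p 0.0857), so the exclusion of chance is weak. Chance could not be excluded for genotype at 4 weeks (7, 9; 20 of 100), labelled sex (2, 9; 80 of 100), genotype on normal diet (3, 8; 52 of 100), diet in control mice (9, 10; 5 of 100), diet in knockout mice (10, 12; 6 of 100) and the interaction (5, 9; 27 of 100).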

How the results depend on the processing

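Fits with a library set, a muscle score or without control 2 and 4 on normal diet were chosen after seeing the data. Outside the fits with 1 library left out, of 826 values of called genes 577 kept direction and side of the threshold, 245 kept direction only and 4 reversed. Of 945 values of genes not called 874 kept both, 33 passed and 38 reversed. Of 351 values of called lists 247 kept both, 103 kept direction only and 1 reversed. Of 998 of other lists 897 kept both, 16 passed and 85 changed direction. With 1 library left out, 1494 of 1805 values of called genes kept both and 311 direction only. Of the genes not called 2071 of 2138 kept both, 21 passed and 46 reversed. For called lists 821 of 895 kept both, 73 kept direction only and 1 reversed. For other lists 2322 of 2485 kept both, 68 passed and 95 changed direction. Among lists past the threshold the median, mean and test differed in sign for 1, muscle markers in the interaction, and among other lists for 8 and 7 (genotype and sex at 4 weeks), 4 and 3 (genotype by diet), 2 and 4 (diet by genotype) and 2 (interaction). Limma-voom shifted the median of all genes by up to 0.11. Simulated 2-fold changes were recovered at 19% for genotype on normal diet and 69% at 4 weeks, and the parts of depth, spread and group size were not separated. The cause was not tested for any change below, apart from fits with fewer samples.

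Same-numbered replicates did not pair: 8 of 36 pairs had a correlation over 0.1 (range -0.57 to 0.58), and 5 correlated best with their own number. With the replicate block the calls were 2 for genotype at 4 weeks, 378 for labelled sex, 157 for genotype on normal diet, 39 for diet in control and 14 in knockout mice, and the lists 3 for genotype at 4 weeks and 0 for sex. With the block Ucp1 (-0.26) and Ppargc1a (-0.080) reversed at 4 weeks, Pparg (0.29) and Lep (-0.038) for sex, Pparg on high fat diet (-0.015), and Suv420h1 (0.022) and Lep (0.058) for diet in knockout mice.

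DESeq2 called 315 genes for genotype at 4 weeks, 884 and 72 on normal and high fat diet, 502 and 166 for diet in control and knockout mice and 12 for the interaction. Ppargc1a on high fat diet (0.0029) and Cidea for diet in control mice (-0.012) reversed with DESeq2, and also with RLE factors (0.0029 and -0.012). Limma-voom called 135 genes for genotype on normal diet and 54 for diet in control mice. Reversed with it were Lep for sex (-0.11), Pparg (-0.031) and Ppargc1a (0.074) on high fat diet, Dio2 for diet in control mice (-0.079), Suv420h1 (0.018) and Lep (0.15) for diet in knockout mice, and Ckm (1.43) and Myh1 (0.91) for the interaction. With no filter Suv420h1 for diet in knockout mice was 0.011.

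At 4 weeks the calls for genotype were 10 in libraries labelled female (2 lists; Ucp1 -0.027), 16 with no sex term (Atp5l -0.21, Cycs -0.039), 218 with the set in place of sex (Atp5l -0.26), 227 with control 1 left out as well (Atp5l -0.32), 9 within the set of 6 (Vwf 0.048, Ppargc1a -0.26) and 22 within the set of 9 (Atp5l -0.59). For sex, Ppargc1a was -0.14 in controls alone. With the set beside sex, 0 genes and 1 list passed, and mt-Rnr2 (0.050), mt-Rnr1 (0.35), Rps12 (-0.77), Atp5l (0.044), Xist (-3.66), Ppargc1a (-0.59), Dio2 (-0.38), Lep (-1.32) and the mitochondrially encoded list (adjusted p = 0.714) reversed.

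With only the groups compared in the fit, the calls were 49 and 26 for genotype on normal and high fat diet and 16 and 142 for diet in control and knockout mice, and the lists 7 and 7 for genotype. Without control 2 and 4 on normal diet they were 84, 24, 25 and 100, with 3 lists for the interaction and Dio2 at -0.092 for diet in control mice. With the muscle score they were 51 for genotype on normal diet and 2 and 9 for diet, with 1, 5 and 1 lists for genotype on normal diet, genotype on high fat diet and the interaction. Reversed with it were Ppargc1a on high fat diet (0.054), Cidea (-0.23) and Dio2 (-0.19) for diet in control and Ppargc1a (0.0039) in knockout mice. Across genes, the correlation of the genotype effects was 0.083 with the set for 4 weeks against normal diet, 0.367 with limma-voom for 4 weeks against high fat diet, and 0.390 with limma-voom, 0.629 in genes of at least 5 CPM and 0.379 without control 2 and 4 for the 2 diets. That of the diet effects was 0.596 in genes of at least 5 CPM and 0.336 without control 2 and 4.

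With 1 library left out, counts of genes ranged from 18 (without knockout 1) to 147 (knockout 2) for genotype at 4 weeks, 2869 to 4216 for sex, 127 (knockout 2 on normal diet) to 888 (control 3 on normal diet) and 10 to 17 for genotype on normal and high fat diet, 21 (control 2 on high fat diet) to 358 (control 3 on normal diet) and 6 (knockout 1 on high fat diet) to 67 for diet in control and knockout mice, and 0 to 2 for the interaction. Counts of lists ranged from 2 to 13 for genotype at 4 weeks, 2 to 8 and 6 to 13 for genotype on normal and high fat diet. At 4 weeks Atp5l ranged from -0.26 to 3.10, Ucp1 from -0.15 to 0.17 and Lep from -0.69 to 0.43, and for sex Ppargc1a from -0.13 to 0.38 and Lep from -0.46 to 0.50. For genotype on normal diet Suv420h1 ranged from -0.24 to 0.0088 and Lep from -2.05 to 0.14. On high fat diet Ckm ranged from -9.51 to 0.51, Pparg from -0.057 to 0.26, Ppargc1a from -0.15 to 0.35, Cidea from -0.091 to 0.13 and the adjusted p of the muscle list from 2.64e-05 to 0.811 (without control 3 on high fat diet). For diet in control mice Cidea ranged from -0.13 to 0.25 and Dio2 from -0.25 to 0.25. In knockout mice Suv420h1 ranged from -0.13 to 0.13, Ppargc1a from -0.45 to 0.17, Dio2 from -0.52 to 0.089 and Lep from -0.66 to 1.63. For the interaction Ckm ranged from -6.42 to 4.10, Myh1 from -4.72 to 1.77, Dio2 from -0.58 to 0.050 and Lep from -1.73 to 0.56.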

Other observations

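All tests in this part were chosen after the result was seen, except those on strain segments and on genes away from the targeted loci. Pttg1, chosen after its values were seen, was low in every knockout library at 4 weeks, at 4.40 to 11.0 CPM against 100 to 235 CPM in control. In older females the knockout libraries on normal diet held 38.8, 4.45, 4.45, 2.35 and 4.74 CPM (replicates 1 to 5) against 66.6 to 144 CPM in control. On high fat diet they held 90.1, 130, 2.31, 79.8 and 3.20 CPM against 77.3 to 97.5 CPM, so Pttg1 did not follow genotype alone. In the second experiment the fold change on normal diet was -3.36 ± 0.95 SE (adjusted p = 0.0671) and the interaction 2.82 ± 1.24 SE (adjusted p = 0.769).

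Genes called at 4 weeks moved the same way in older females as sets. The genes called higher were higher in the knockout on normal diet (35 of 51 positive, median 0.39, adjusted p = 3.1e-05; 0.0307 with an estimated correlation) and on high fat diet (43 of 51, median 0.39, adjusted p = 1.7e-18; 1.2e-04 with an estimated correlation). Those called lower were lower on normal diet (30 of 33 negative, median -0.49, adjusted p = 3.7e-06; 5.1e-04) and on high fat diet (33 of 33, median -0.46, adjusted p = 4.5e-13; 5.1e-06). Within the set of 9 libraries of the first experiment, Xist was lower in knockout (177 ± 14.5 CPM, n = 4) than in control libraries (313 ± 38.8 CPM, n = 5; exact permutation p = 0.0079). In the fits of all 15 libraries it was not called, at -1.47 (adjusted p = 0.585) with sex and -1.56 (adjusted p = 0.447) with the library set. In the second experiment its fold changes were -0.01 (adjusted p = 0.987) on normal and -0.21 (adjusted p = 0.999) on high fat diet.

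A set of 15 genes was called in the knockout in the first experiment and in at least 1 diet of the second, among them Wdfy1, Rps3a3, Ifi27l2a, Akr1c13, St6galnac5, Maoa, Siae and Eps8l1. Against linkage to the targeted loci as the cause for the whole set, 1 of 15 lay within 10 Mb of a targeted locus (Fisher's exact p = 0.283). For Eps8l1, which ends 0.26 Mb before Suv420h2, linkage stays open. It also stays open for Gm15510 (chromosome 7, 5046949 to 5057116), just beyond Suv420h2 (4740115 to 4747514) and not in the set of 15. Gm15510 and Eps8l1 were the decreases called on both diets, and Gm15510 had no count in the 5 knockout libraries on normal diet. Sbk2 (chromosome 7, 4940512 to 4964406) lies between Suv420h2 and Gm15510, but its call on normal diet was lost with the muscle score as a covariate. Segments of another strain's genome elsewhere could also be a cause: 0 of 14 genes away from the targeted loci had another of the set within 2 Mb, but random sets also gave a median of 0, so the bound written beforehand could not discriminate. Loss of the enzymes stays open: of genes away from the loci called at 4 weeks, 76.8% (63 of 82) had the same sign on normal diet, above the bound of 3 in 4 written beforehand, but 61.1% with the library set, 72.2% with limma-voom and 73.2% without control replicates 2 and 4 were below it, against 53.7% of all genes, and strain segments carried by all knockout mice would also give a shared sign.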
